A study of Mus musculus with 8 samples.

How the data were processed

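Messenger RNA bound to ribosomes was measured in the ventral tegmental area (VTA), the midbrain region that holds dopamine neurons projecting to the striatum and cortex. Male mice of 2 genotypes, Ogt flox+/Y and Ogt flox-/Y, received 2 adeno-associated viruses. The first expresses Cre recombinase under the tyrosine hydroxylase promoter. The other carries a Cre-dependent, HA-tagged ribosome-binding fusion protein (NBL10), through which ribosomes of the cells with Cre are enriched. Libraries were grouped by the genotype in their labels into 4 Ogt knockdown libraries (flox+/Y, replicates 2, 3, 4 and 5) and 4 control libraries (flox-/Y, replicates 3, 4, 5 and 6). No label says that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

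The authors deposited 1 table of whole-number read counts per gene for all 8 libraries. Counts were made with featureCounts 2.0.3 over the exons of the GENCODE vM30 mouse annotation, per the file headers. The command line in the header holds no option for strand, for pairs as units or for reads with several alignments. Reads were therefore counted without strand and as single mates, and reads with several alignments were not counted. FastQC, Trimmomatic, STAR and the genome build mm10 are named per the submitters' processing notes, with no versions. GENCODE vM30 describes GRCm39, a later build than mm10, and this conflict was not resolved. Of 56 respiratory chain symbols in a fixed list, 48 were found by name in the deposited table. These 48 had a lowest mean of 56.5 CPM (counts relative to the size of the library), which does not settle the conflict. Coordinates are those of the table (GRCm39). Gene symbols and GC content came from the GENCODE M21 annotation and transcripts, matched by gene ID, so some symbols are older ones, such as Mgea5 for Oga. Of 56691 gene IDs, 52073 matched a symbol and 4618 did not. The unmatched IDs held between 0.33% and 1.81% of the reads of a library.

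Total counts per library ranged from 49802305 to 147747191 reads. A count of 3 reads, used as the floor of detection, corresponds to between 0.0203 and 0.0602 CPM, for counting error only. Same-group libraries were compared with a chi-square test of their counts over genes. The statistic per degree of freedom was 22.9 to 420, so none were duplicates.

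Genes were filtered with filterByExpr, which left 19912. Counts were scaled by trimmed mean of M values (TMM) and tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, the quasi-likelihood F test, two-sided) in R 4.3.3. Benjamini-Hochberg adjustment was made over all genes tested, with a threshold of 0.05. Fold changes are Ogt knockdown over control, and CPM values are TMM-scaled. The 36 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and adjustment over the 36 lists. Camera with an estimated correlation and fry were run beside it. Markers of 12 cell types were also scored per library, as the mean of standardised log2 CPM, and compared by exact two-sided permutation over the 70 assignments of the 8 libraries.

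The expected steps, lists, tests and the rule for named genes were fixed before the data were examined. That rule names Ogt, Oga, Stat3, Th, Slc6a3, Ddc and Slc18a2 in any case. It adds the 12 genes with the largest fold in each direction, among those past the threshold whose groups do not overlap, with a mean log2 CPM above 0 and a symbol that is not a predicted model. It further adds the 5 genes with the smallest p in each direction, up to 4 members with the smallest p of each list, and members stated as exceptions to a count. Any other gene is said to have been chosen after its values were seen.

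Alternatives were RLE and upper quartile scaling, no filter and a strict filter (CPM of at least 1 in at least 4 libraries), DESeq2 1.42.0, limma-voom with sample quality weights, estimation that is not robust, the replicate number as a block, a non-neuronal marker score or 1 surrogate variable (sva 3.50.0) as a covariate, other thresholds, and leaving out each library in turn. A correction for GC content and gene length, and leaving out both libraries numbered 3, were added after seeing the data. Scoring the cell types per library under these alternatives was not planned either. Respiratory chain members listed under newer symbols, Il1b, Il6 and Tnf were among the list members that were not tested.

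The test was tried on simulated data with the means and library sizes of these 8 libraries (19407 genes). Simulated changes were called in the right direction for 3% of 67 genes at 1.5-fold, 47.8% of 67 genes at 2-fold and 84.8% of 66 genes at 4-fold. Of 94 calls, 4 were of unchanged genes (4.3%). A simulated list raised 1.5-fold had an adjusted p of 3.45e-11, and 0 of 20 unchanged simulated lists were called. Simulated genes were drawn independently of each other. In the real lists the estimated correlation between genes ranged from -0.012 (cholesterol synthesis) to 0.912 (astrocyte markers). Few simulated genes were changed, against 28.5% of the real genes tested. These rates therefore need not hold for the real data.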

Results

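The data are read counts of ribosome-associated mRNA from the mouse ventral tegmental area, enriched for dopamine neurons through a tagged ribosome-binding protein that depends on Cre under the tyrosine hydroxylase promoter. The libraries also hold messages of other cells. Libraries of mice with a floxed Ogt gene (Ogt knockdown, n = 4) were compared with libraries of mice without it (control, n = 4), all male. The comparison asks which of the enriched messages change when Ogt is knocked down. Ogt encodes O-GlcNAc transferase, the enzyme that attaches the sugar O-GlcNAc to proteins, among them the transcription factor STAT3 that the study is about. Control replicates 3, 4, 5 and 6 held 76143832, 49802305, 129801354 and 147747191 reads. Ogt knockdown replicates 2, 3, 4 and 5 held 94485291, 55397971, 72018591 and 81447176.

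The Ogt message itself (ENSMUSG00000034160.14, chromosome X, 100683666 to 100727957, GRCm39) was lower in every knockdown library than in every control library. Control replicates 3, 4, 5 and 6 had 159.4, 117.9, 118.3 and 108.3 CPM. Knockdown replicates 2, 3, 4 and 5 had 74.4, 47.2, 41.7 and 36.0 CPM. The mean fell from 126 ± 22.8 to 49.8 ± 17.0 CPM (SD, n = 4 each), a log2 fold change of -1.34 (SE 0.23, edgeR quasi-likelihood adjusted p = 0.00243). The count covers all exons of the gene, and which exons are floxed is not given in the sources used here. Oga, listed as Mgea5, encodes the enzyme that removes the sugar. It fell from 150.8 ± 6.76 to 58.6 ± 11.4 CPM (SD, n = 4; log2 fold change -1.36, SE 0.15, edgeR adjusted p = 0.00041).

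**Figure D1:**
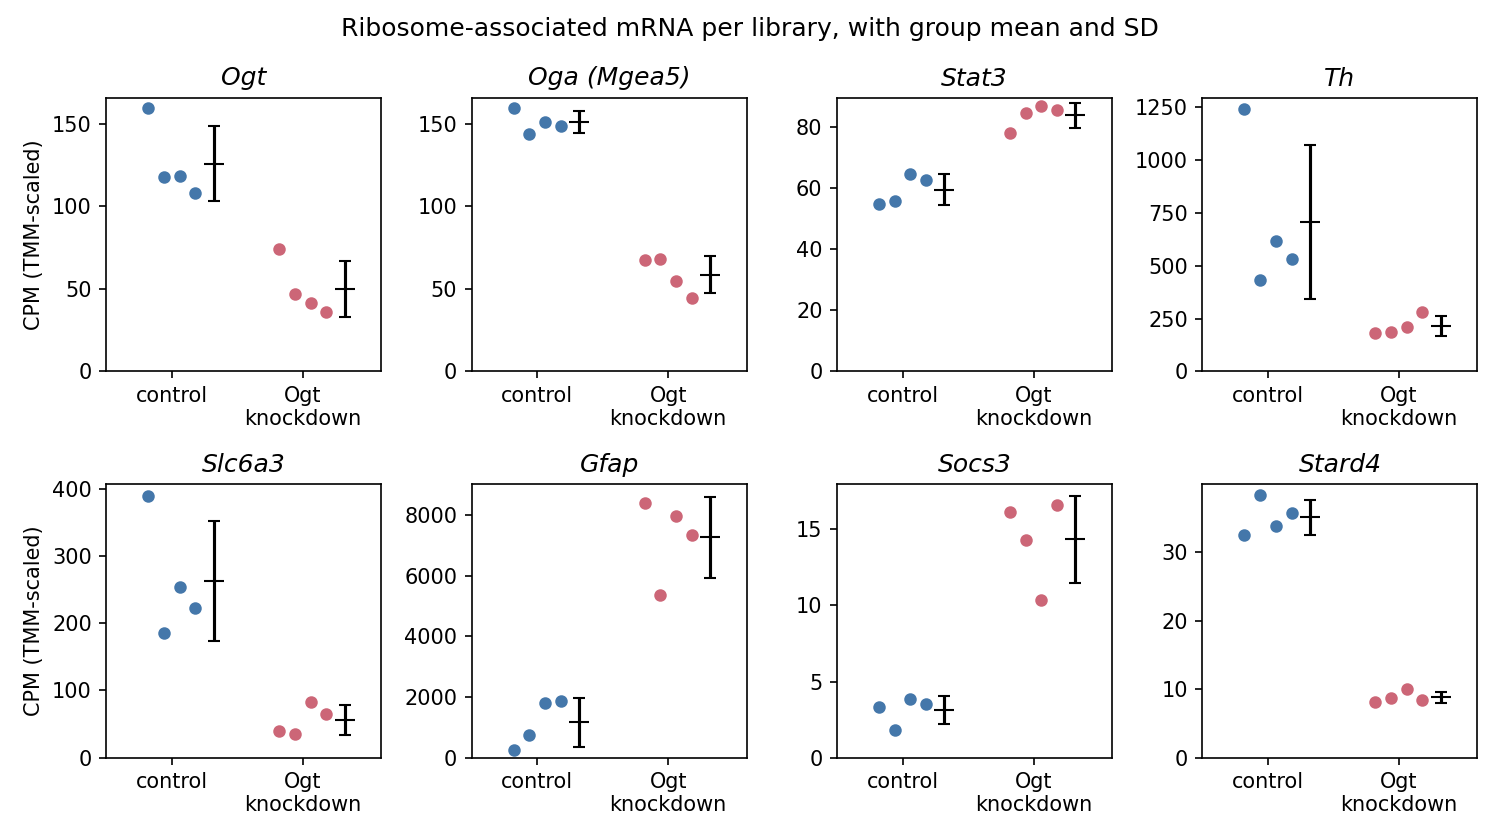
CPM (TMM-scaled, linear axis from 0) of 8 genes in each of the 4 control and 4 Ogt knockdown libraries (points), with the group mean and SD (black bars). The groups do not overlap for any of the 8 genes. Ogt lies between 108.3 and 159.4 CPM in controls and between 36.0 and 74.4 CPM in knockdown libraries.

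Of 17 measured members of the O-GlcNAc and hexosamine list, Ogt and Oga included, 6 fell and 2 rose, and 9 did not pass the test; the counts were 6 and 2 adjusted over the list alone. The 8 changed members became 5 without control replicate 4 and 4 without control replicate 5 or 6 or knockdown replicate 2. Gnpda1, a glucosamine-6-phosphate deaminase, fell 1.44-fold and the 2 that rose were Renbp, an N-acetylglucosamine epimerase (2.01-fold), and Slc35a3, whose call was lost without any library but control replicate 3 or knockdown replicate 5 (adjusted p = 0.0564 to 0.132). The list as a whole did not pass camera (adjusted p = 0.0556, and 0.349 with an estimated correlation). It passed when control replicate 4 (adjusted p = 0.0382), control replicate 5 (0.0402), knockdown replicate 3 (0.049) or knockdown replicate 5 (0.0464) was left out, and with no filter on low counts (0.0125).

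Across the transcriptome, lists of dopamine neuron and synaptic release messages passed camera as lower, and lists of immune, microglia and astrocyte messages as higher. With an estimated correlation none of these lists passed (adjusted p = 0.295 to 0.483). Of 19912 genes tested, 5668 changed (28.5%), 2659 higher and 3009 lower in knockdown. With upper quartile scaling, 3176 were higher and 2432 lower. Without control replicate 4 the higher genes numbered 1684 and without control replicate 6 they numbered 1736. Without both libraries numbered 3, which lie apart from the rest, 9565 genes changed, 4805 higher and 4760 lower. A fold of 2 or more was seen for 1568 of the higher and 1048 of the lower genes. The groups did not overlap for 93.1% of the changed genes and 35.1% of all genes tested, against 2.86% by chance. The largest rise among the genes named by the fixed rule was that of A2m, alpha-2-macroglobulin, a protease inhibitor, from 16.2 ± 7.59 to 473.5 ± 124.4 CPM (SD, n = 4, 29.1-fold). Other large rises were those of the chemokine genes Ccl7 (22.9-fold) and Ccl2 (22.5-fold), Clec7a (19.1-fold), Lgals3 (18.6-fold), H2-Aa (17.9-fold), Cst7 (17.5-fold) and Ahnak (16.5-fold). The rule also named Olfr56 (24.8-fold), Lcn2 (22.4-fold), Igkc (18.8-fold) and Tgm1 (18.1-fold). Mean control levels were low for Igkc (0.1132 CPM), Olfr56 (0.1871), Clec7a (0.2581), Cst7 (0.2665) and Ccl7 (0.3002). The size of their folds is therefore uncertain. Igkc had 0.3519 CPM in control replicate 3 and 0 to 0.08487 in the other controls. Olfr56, Ccl7 and Tgm1 had 0 CPM in control replicate 3. Tgm1 had 3.165 to 3.65 CPM in the other controls. Lcn2 rose 7.74-fold without knockdown replicate 3, and its call was lost without control replicate 5 (edgeR adjusted p = 0.0503). Without knockdown replicate 3, Ccl7, Ccl2 and H2-Aa rose 12.7-fold, 10.7-fold and 9.89-fold, and without control replicate 5 Ccl7 rose 35.6-fold. The largest fall named by that rule was of Cldn34c1, from 3.243 ± 0.6824 to 0.2455 ± 0.4402 CPM (SD, n = 4, 14.01-fold). Next were Sprr1a (10.14-fold, and 5.81-fold without control replicate 4) and Ccer2 (10.12-fold). Chrnb3, a nicotinic receptor subunit, fell 9.77-fold. The peptide genes Ucn and Cartpt fell 8.53-fold and 6.48-fold (Cartpt 4.31-fold without control replicate 3). Ppm1j (8.75-fold), Htr3a (7.57-fold), Vill (6.95-fold), Rassf6 (6.89-fold), Hsd17b2 (6.67-fold) and Rgs11 (6.45-fold) were named too. Kcnab3, a potassium channel subunit named for its small p, fell 6.18-fold. Kcnab3, Diras1, Stard4, Ggta1 and Ttll9 were among the genes that shared the smallest adjusted p (9.13e-05, edgeR).

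Most dopamine neuron identity genes fell. Of 35 measured members, 24 fell, 2 rose and 9 did not pass the test (26 and 3 adjusted over the list alone). Th, which encodes the rate-limiting enzyme of dopamine synthesis, fell from 707 ± 364 to 214 ± 47.3 CPM (SD, n = 4; log2 fold change -1.72, SE 0.32, edgeR adjusted p = 0.00351). Ddc, the next enzyme of the pathway, fell 5.01-fold. Slc6a3, the dopamine transporter, fell 4.72-fold and Slc18a2, the vesicular monoamine transporter, 3.98-fold. The 2 members that rose were Aldh1a1 (2.30-fold) and Otx2 (1.51-fold). The Otx2 call was lost when any library other than control replicate 3 was left out, with adjusted p from 0.0524 to 0.14. The list passed camera (adjusted p = 3.57e-08; adjusted p = 0.349 with an estimated correlation). Control replicate 3 was highest for Th, Ddc, Slc6a3 and Slc18a2. It had 1241 CPM of Th, against 435 to 619.4 in the other controls. Without that library the median log2 fold change of the list was -0.92, against -1.159 with it. Then 24 members fell and 3 rose. With the replicate number as a block, Th, Slc6a3 and Otx2 missed the threshold (adjusted p = 0.0684, 0.0583 and 0.207). That fit takes the group difference only from the replicate numbers that both groups hold, which include control replicate 3. It leaves few degrees of freedom, so a lost call there may reflect low power. The mean log2 CPM of astrocyte, oligodendrocyte and microglia markers was higher in these knockdown libraries, by 1.31, 0.81 and 1.91 (astrocytes 0.78 without control replicate 3).

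The synaptic vesicle release list fell furthest past its test of all 36 lists. Of 36 members, 30 fell, 0 rose and 6 did not pass (31 lower adjusted over the list alone), with a camera adjusted p of 1.44e-12 and an adjusted p = 0.298 with an estimated correlation. Vamp1 fell from 899 ± 137 to 191 ± 31.0 CPM (SD, n = 4, 4.71-fold), and Syt2, Cplx1 and Sv2a fell 4.10-fold, 4.01-fold and 2.79-fold. Some markers of other neurons fell too. Of 19 GABA neuron markers, 8 fell and 1 rose (8 and 1 adjusted over the list alone), among them Slc32a1 (2.20-fold) and Gad1 (2.13-fold), while Nkx2-2 rose, with a camera adjusted p of 0.0383 and an adjusted p = 0.49 with an estimated correlation. That call was lost without control replicate 4 (adjusted p = 0.0902), control replicate 6 (0.0674) or knockdown replicate 2 (0.0976). Of 16 glutamate neuron markers, 5 fell and 0 rose (6 lower adjusted over the list alone), namely Nefm (3.91-fold), Slc17a6 (2.03-fold), Slc30a3, Slc17a8 and Rbfox3 (list adjusted p = 0.0205, and adjusted p = 0.378 with an estimated correlation). Of 13 serotonin, noradrenaline and acetylcholine neuron markers, 5 fell and 0 rose (5 adjusted over the list alone), namely Tph2 (6.30-fold), Slc6a4 (3.74-fold), En1, Fev and Chat. En1 is also a member of the dopamine neuron list. This list had a camera adjusted p of 0.0228 and an adjusted p = 0.483 with an estimated correlation; without control replicate 4 the adjusted p was 0.0671. The call of Nkx2-2 was lost without control replicate 6 or knockdown replicate 4 or 5 (adjusted p = 0.0518 to 0.0755). That of Rbfox3 was lost without any library but control replicate 3 or knockdown replicate 5 (0.0567 to 0.111), and that of Chat without control replicate 4, 5 or 6 or knockdown replicate 4 or 5 (0.0694 to 0.121). Rbfox3 and Chat were chosen after their values were seen. In mean log2 CPM, control replicate 3 lay below every knockdown library for GABA (3.255, knockdown 3.465 to 4.08), glutamate (3.241, knockdown 3.311 to 3.588) and serotonin, noradrenaline and acetylcholine neuron markers (0.551, knockdown 0.735 to 1.24). The exact permutation p of these levels was 0.4, 0.143 and 0.143. Without that library, 10, 8 and 10 members of these lists fell. In the same knockdown libraries the mean log2 CPM of astrocyte, oligodendrocyte and microglia markers was higher than in controls, by 1.31, 0.81 and 1.91 (astrocytes 0.78 without control replicate 3).

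Genes of the JAK-STAT3 pathway and STAT3 targets rose in part. Of 39 members, 18 rose, 5 fell and 16 did not pass (18 and 5 adjusted over the list alone), with a camera adjusted p of 0.0038 and an adjusted p = 0.349 with an estimated correlation. Stat3 rose from 59.5 ± 4.94 to 83.8 ± 4.04 CPM (SD, n = 4; log2 fold change 0.49, SE 0.11, edgeR adjusted p = 0.0083). Socs3, a feedback inhibitor induced by STAT3, rose 4.57-fold. Osmr, the oncostatin M receptor, rose 4.08-fold, Bcl3 3.93-fold and Jak2 1.69-fold. The 5 members that fell were Pim1 (2.09-fold), Ccnd1 (1.97-fold), Pias3 (1.42-fold), Jak1 (1.39-fold) and Stat5b (1.30-fold). Jak1 and Stat5b missed the threshold with upper quartile scaling (adjusted p = 0.0741 and 0.07). Jak1 also missed it without control replicate 3, 4, 5 or 6 or knockdown replicate 2 or 5 (adjusted p = 0.054 to 0.104), and Stat5b without control replicate 4, 5 or 6 or knockdown replicate 2 or 4 (0.0618 to 0.104). Pias3 missed it without control replicate 4 (0.0567) or knockdown replicate 5 (0.052). With the replicate number as a block, Stat3 (0.0752), Jak2 (0.0715) and Osmr (0.0526) were among those that missed it. Markers of astrocytes and microglia were higher in the same libraries, with median log2 fold changes of 1.02 and 2.27.

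Most interferon-stimulated genes and inflammatory mediators rose. Of 34 interferon-stimulated genes, 18 rose and 0 fell (27 higher adjusted over the list alone), with a camera adjusted p of 1.46e-09 and an adjusted p = 0.378 with an estimated correlation. Ifitm3 rose 3.90-fold, the class I antigen presentation genes H2-K1 and H2-D1 3.41-fold and 2.78-fold, and Irf7 2.45-fold. H2-K1 and H2-D1 are near-identical in part, so their counts are uncertain. Of 26 inflammatory mediators, 19 rose and 0 fell (20 higher adjusted over the list alone), with a camera adjusted p of 1.3e-08 and an adjusted p = 0.295 with an estimated correlation. Complement C3 rose 6.48-fold, Tlr2 4.73-fold, Nfkb2 3.41-fold and Tnfaip3 2.97-fold. Ccl2 and Ccl7 varied widely in knockdown libraries (19.4 ± 20.8 and 7.24 ± 6.77 CPM, SD, n = 4). The mean log2 CPM of microglia and astrocyte markers was higher in the same libraries, by 1.91 and 1.31 (astrocytes 0.78 without control replicate 3).

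Most markers of microglia and oligodendrocytes rose, and some of astrocytes. Of 27 microglia and macrophage markers, 21 rose and 0 fell (23 higher adjusted over the list alone), with a median log2 fold change of 2.27, a camera adjusted p of 2.02e-09 and an adjusted p = 0.349 with an estimated correlation. Their levels were low: Tyrobp rose from 0.63 ± 0.31 to 6.33 ± 3.38 CPM and Cx3cr1 from 1.31 ± 0.28 to 6.32 ± 2.56 CPM (SD, n = 4). Of 25 astrocyte markers, 8 rose and 0 fell (14 higher adjusted over the list alone), with a median of 1.02, a camera adjusted p of 2.71e-05 and an adjusted p = 0.483 with an estimated correlation. Gfap, the intermediate filament of astrocytes, rose from 1162 ± 796 to 7270 ± 1339 CPM (SD, n = 4, 6.25-fold). Gjb2 rose 3.86-fold. The astrocyte values depend on single libraries, above all on control replicate 3, where these markers lay lowest (5.49 in mean log2 CPM, other controls 7.60). Without it 16 rose and the median was 0.737. Without control replicate 4 or 6 the count was 3 or 4, and without knockdown replicate 2, 3, 4 or 5 it was 3, 5, 3 or 4. Of 28 oligodendrocyte markers, 17 rose and 0 fell (20 higher adjusted over the list alone), with a median of 0.84, a camera adjusted p of 3.46e-06 and an adjusted p = 0.384 with an estimated correlation. Cryab rose 4.33-fold, Trf 2.67-fold and Cnp 1.82-fold. The 17 oligodendrocyte markers became 8 without control replicate 4 or 6 or knockdown replicate 2, and 11 without knockdown replicate 4. Scored per library, the dopamine, astrocyte, oligodendrocyte and microglia markers each separated all 4 knockdown from all 4 control libraries (exact permutation p = 0.0286, the smallest this design allows; 0.0857 adjusted over 12 cell types). None of the 12 passed after adjustment with all 8 libraries, and 7 passed without control replicate 3, a setting not planned for this test. At its smallest p this test passes adjustment only if enough lists reach that p together. With 4 lists there, 0.0857 was the lowest adjusted p possible, however far apart the groups lay. The counts of lists passed therefore say little about single cell types.

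**Figure D2:**
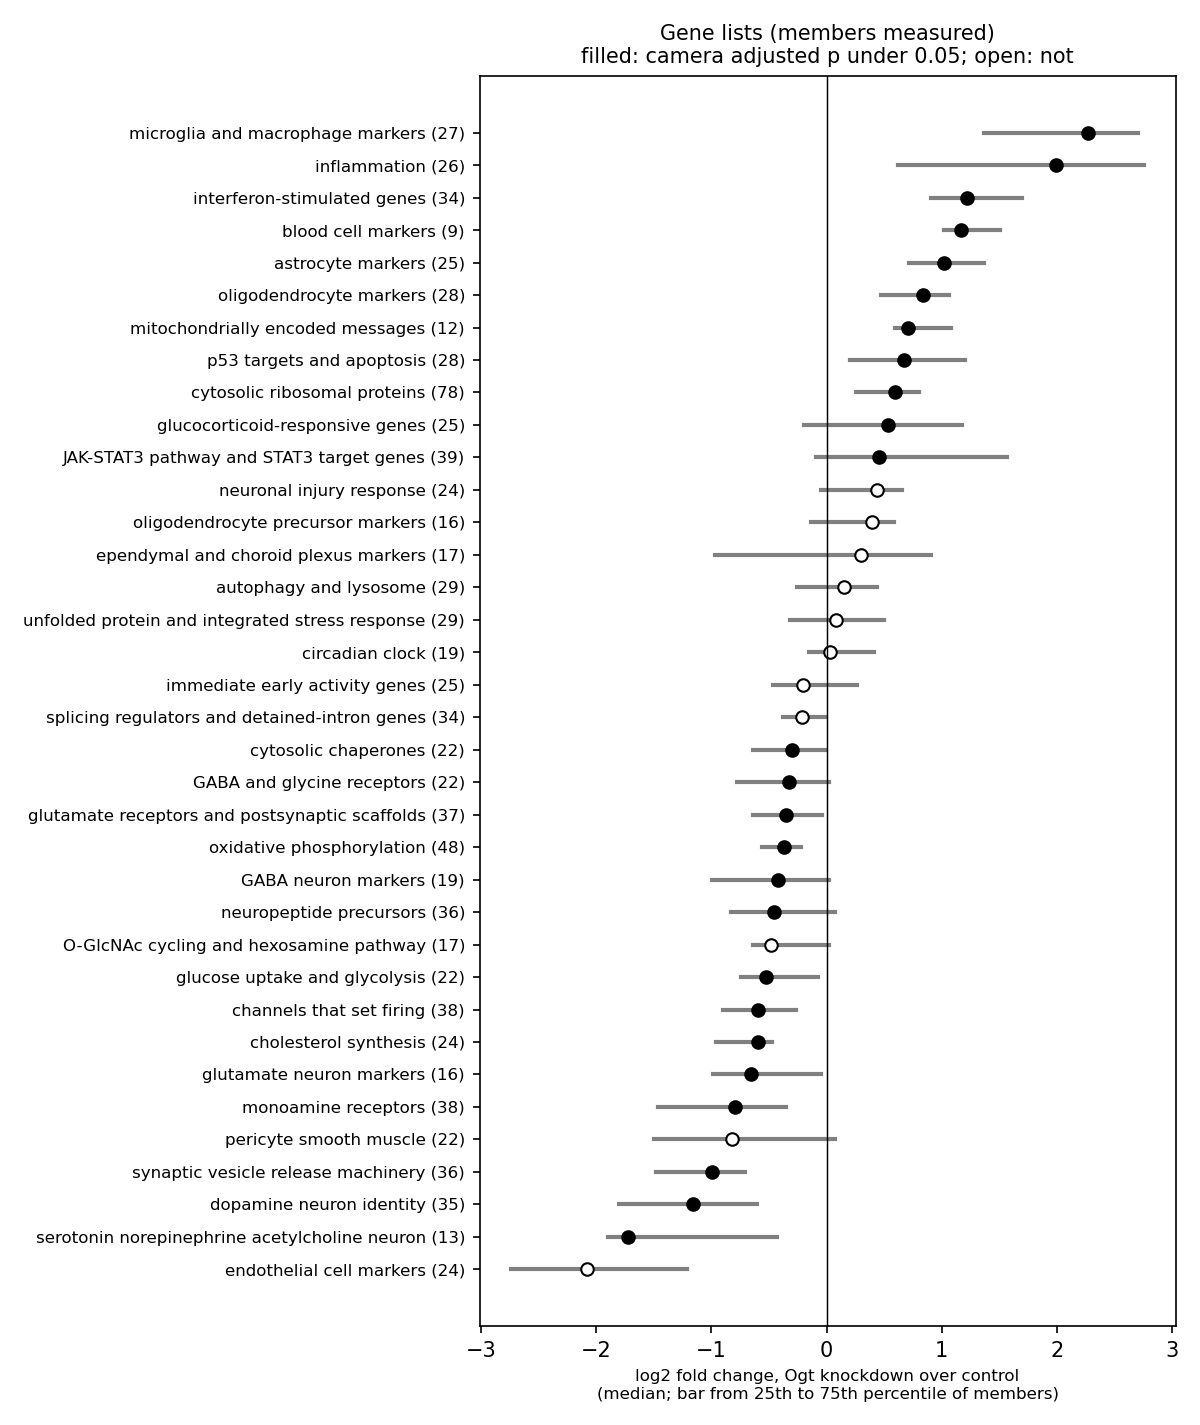
Median log2 fold change (Ogt knockdown over control, x axis) of the measured members of each of the 36 gene lists, whose number is in brackets, with bars from the 25th to the 75th percentile. Filled points passed camera with the preset correlation (25 lists) and open points did not. Microglia markers stand highest (2.27), and the endothelial list, which did not pass, lowest (-2.08).

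Blood vessel markers depended on a single library. Control replicate 3 had 150.8 CPM of Cldn5, 201.6 of Flt1 and 248.4 of Rgs5, 3 vascular genes chosen after their values were seen. The other control libraries had at most 2.88, 4.28 and 5.23 CPM. With it, 1 of 24 endothelial markers fell, Spock2 (2.42-fold), and 0 rose (1 and 0 adjusted over the list alone), with a median of -2.08 and a camera adjusted p of 0.415. Without it, 13 rose and 1 fell, the median was 1.005 and the adjusted p was 0.000726 (0.217 with an estimated correlation). Of 22 pericyte, smooth muscle and vascular fibroblast markers 1 fell, Mcam (2.19-fold), and 0 rose (0 adjusted over the list alone). The median of that list was -0.82 while camera pointed upward (adjusted p = 0.722), so median and test differ in sign. Without control replicate 3, 7 rose and 1 fell (adjusted p = 0.00527, and 0.346 with an estimated correlation); without control replicate 4, 2 members changed. The Mcam call was lost without knockdown replicate 2, 3 or 5 (adjusted p = 0.0563, 0.0581 and 0.0652). The remaining cell type lists were those of oligodendrocyte precursors (Bcas1, Xylt1 and Vcan higher and C1ql1 lower of 16, the same 3 and 1 adjusted over the list alone; adjusted p = 0.165), of ependyma and choroid plexus (Rarres2, Otx2 and Kcne2 higher and Prlr lower of 17, 1 and 0 adjusted over the list alone; adjusted p = 0.343) and of blood (9 measured members, 0 of them changed adjusted over the list alone; adjusted p = 0.0383, and adjusted p = 0.378 with an estimated correlation). The call of the blood list was lost with upper quartile scaling (adjusted p = 0.0653), the strict filter (0.071) and the GC and length correction added after seeing the data (0.0534). The calls of Vcan, Kcne2, Prlr and Otx2 were each lost without any of at least 5 single libraries, with adjusted p of up to 0.138 (without control replicate 4), 0.132 (knockdown replicate 2), 0.0864 (control replicate 6) and 0.14 (knockdown replicate 2). Without control replicate 3, 8 ependymal and 8 blood markers changed. The ependymal count was 1 without control replicate 4 or knockdown replicate 4 or 5, and 2 without control replicate 5 or 6 or knockdown replicate 2.

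**Figure D3:**
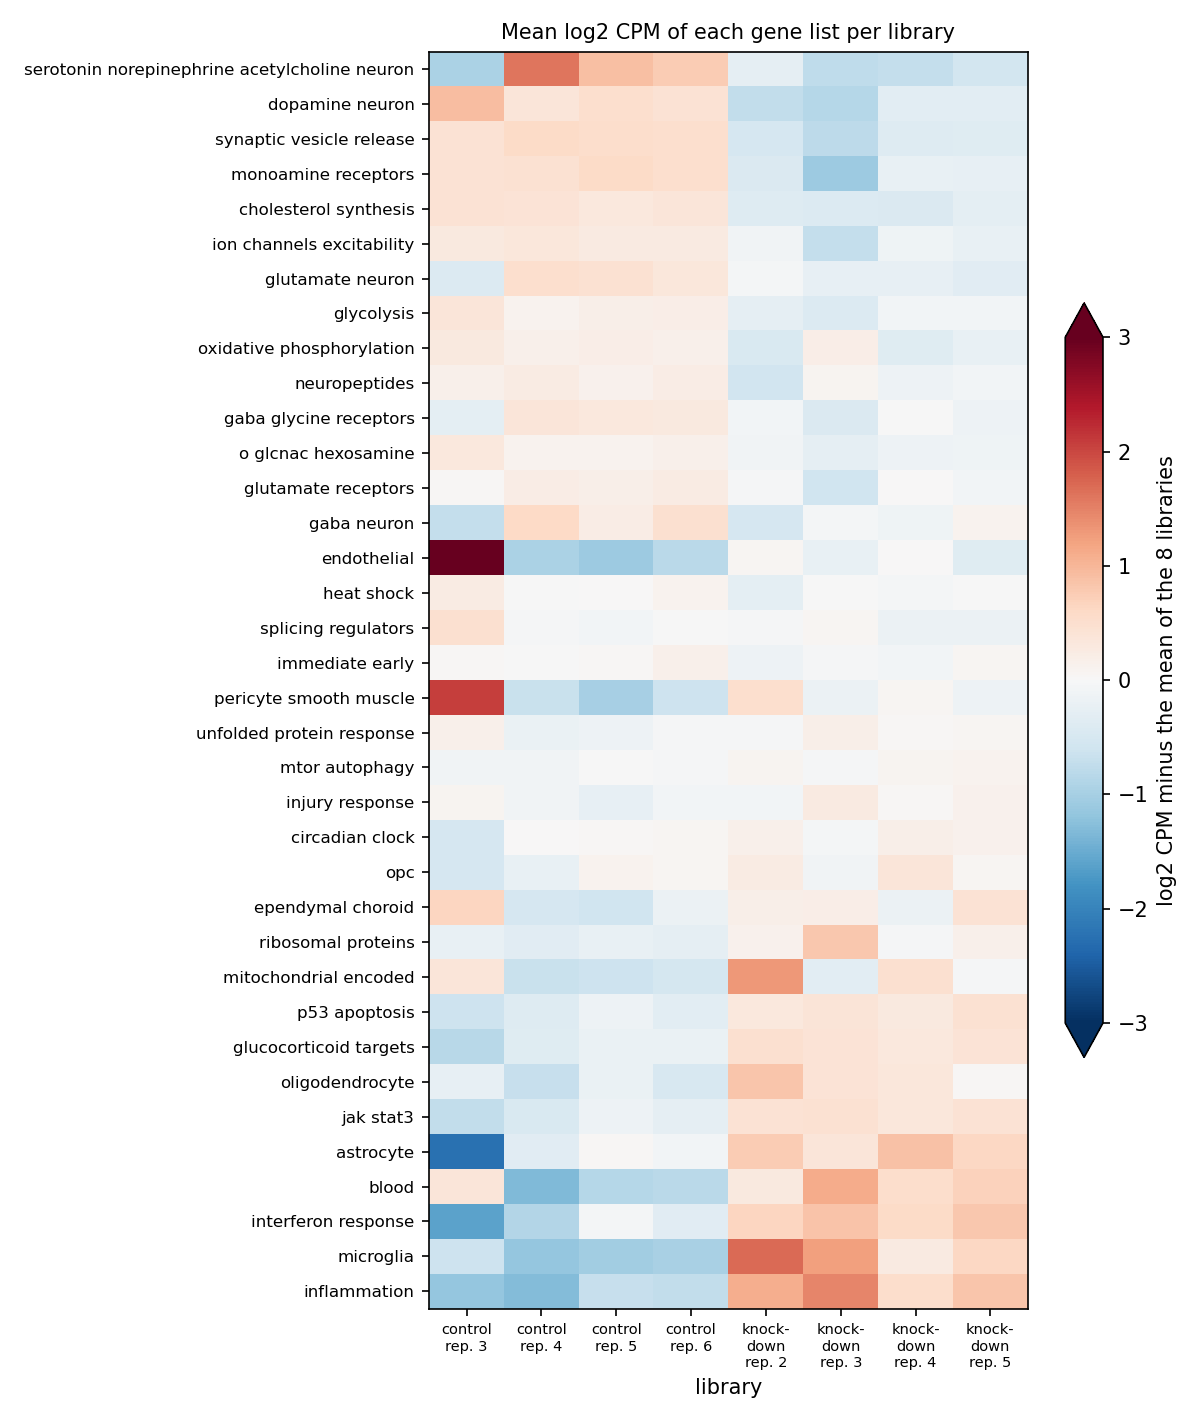
Mean log2 CPM of each of the 36 gene lists (rows) in each of the 8 libraries (columns), minus the mean of the 8 libraries, on a scale from -3 to 3. Control replicate 3 stands apart from the other 3 controls in the endothelial list (6.58 against a mean of 2.27 log2 CPM) and the astrocyte list (5.49 against 7.60).

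Most cholesterol synthesis genes fell. Of 24 members, 18 fell, 0 rose and 6 did not pass (19 lower adjusted over the list alone). Stard4, a sterol carrier, fell from 35.2 ± 2.56 to 8.81 ± 0.86 CPM (SD, n = 4, 3.99-fold), Insig1 fell 2.26-fold and Sqle, squalene epoxidase, 1.79-fold. The camera adjusted p was 5.48e-08. This was the 1 of the 25 list calls that held with an estimated correlation (adjusted p = 0.0264), and it was lost there without control replicate 3 (adjusted p = 0.0788). In the same libraries the mean log2 CPM of astrocyte, oligodendrocyte and microglia markers was higher, by 1.31, 0.81 and 1.91 (astrocytes 0.78 without control replicate 3).

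Some genes of energy metabolism fell and some of ribosomal proteins rose. Of 48 nuclear genes of the respiratory chain and ATP synthase, 18 fell and 0 rose (19 lower adjusted over the list alone), such as Ndufs8 (1.97-fold) and Atp5b (1.87-fold). The mean log2 CPM of this list in knockdown replicate 3 (8.412) lay within the control range (8.354 to 8.508), against 7.76 to 7.993 in the other knockdown libraries (exact permutation p = 0.0857). Without knockdown replicate 3, 39 members changed, and without control replicate 6, 11. The list had a camera adjusted p of 2.22e-06 and an adjusted p = 0.483 with an estimated correlation. Of 22 glycolysis genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone), with a camera adjusted p of 0.00172 and an adjusted p = 0.378 with an estimated correlation. Eno2, the neuronal enolase, fell 2.50-fold and Pkm 2.46-fold, while Hk2 rose, a call lost without control replicate 5 or 6 or knockdown replicate 2 or 4 (adjusted p = 0.0532 to 0.0666). Of 78 ribosomal protein genes, 37 rose and 0 fell (44 higher adjusted over the list alone), such as Rps19 (2.92-fold) and Rpl12 (2.25-fold; 19, 24 and 21 changed without control replicate 4, 5 and 6), with a camera adjusted p of 2.27e-08 and an adjusted p = 0.483 with an estimated correlation. In mean log2 CPM, knockdown replicate 3 was highest for the ribosomal list (8.677, other knockdown libraries 7.825 to 8.009). Of 12 mitochondrially encoded messages 1 rose, mt-Nd3, and 0 fell (1 adjusted over the list alone). Its level was low, 1.27 ± 0.39 CPM in controls and 2.84 ± 0.68 CPM in knockdown libraries (SD, n = 4, 2.24-fold). The list had a camera adjusted p of 0.0244 and an adjusted p = 0.499 with an estimated correlation. Genes of the mitochondrial chromosome held 0.27% to 0.71% of the reads of knockdown libraries. In control replicate 3 they held 0.36%, and in the other controls 0.19% to 0.20%. Whether this share reflects the purity of the enriched messages was not tested. The mt-Nd3 call was lost without control replicate 6 (adjusted p = 0.0685) or knockdown replicate 2 (0.0678) or 4 (0.0512). The call of that list was lost without control replicate 4 (adjusted p = 0.0502), control replicate 5 (0.0535) or knockdown replicate 2 (0.0976), and with the GC and length correction that was added after seeing the data (0.166). Without control replicate 3 it stayed past the threshold (0.00504), 8 of 12 rose and the median went from 0.705 to 1.143. Without knockdown replicate 3 or 5, 2 members changed. Astrocyte, oligodendrocyte and microglia markers were higher in the knockdown libraries, with medians of 1.02, 0.84 and 2.27. Ribosomal protein and mitochondrial genes have near-identical copies elsewhere in the genome, so their counts are uncertain.

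Some targets of p53 and apoptosis genes rose. Of 28 members, 14 rose, 1 fell and 13 did not pass (16 and 1 adjusted over the list alone), with a camera adjusted p of 2.17e-05 and an adjusted p = 0.349 with an estimated correlation. Trp53inp1 rose 2.55-fold, the pro-apoptotic genes Bax and Bbc3 2.49-fold and 2.11-fold, and Mdm2, the ubiquitin ligase of p53, 2.41-fold. The member that fell was Cycs, cytochrome c. Of 25 glucocorticoid-responsive genes, 11 rose and 0 fell (11 and 1 adjusted over the list alone), such as Angptl4 (2.99-fold) and Cdkn1a (2.15-fold), a gene shared with the p53 list. The 11 became 6 changed genes without control replicate 4 and 7 without knockdown replicate 2. That list had a camera adjusted p of 0.0268 and an adjusted p = 0.384 with an estimated correlation. Astrocyte and microglia markers were higher in the same libraries, with the medians of 1.02 and 2.27.

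All of these values come from 1 comparison of 4 against 4 libraries by edgeR's quasi-likelihood test and camera. The biological coefficient of variation was 38.1%. With a non-neuronal marker score as a covariate, edgeR called 0 genes, with 2099 at an unadjusted p under 0.05 against 8001 without it. The log2 fold change of Ogt was then -2.54 (adjusted p = 0.267); the score was -0.68 to -0.31 in the control and 0.18 to 0.81 in the knockdown libraries, so it separated the groups. DESeq2 and limma-voom, run without that score, called 6861 and 10218 genes.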

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

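The count over splits was planned, with its bound written afterwards, and the vascular genes outside the fixed lists were chosen after the vascular lists were seen but before their own values were; all other tests in this part were chosen after the result they measure was seen. A library was taken to lie far from its group by Dixon's test, the gap to its neighbour over the range of the group. This was done in 72 groups of list values and 294 groups of gene values. In groups of 4, chance marks about 1 in 20 as holding a library far from the rest.

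The fall of neuronal messages and the rise of glial ones is the main pattern. A smaller share of neurons, with all other cell types otherwise unchanged, would raise glial markers alike if neurons held little of them. Microglia markers rose further than oligodendrocyte markers, by 1.10 on the log2 scale (SE 0.24, exact permutation p = 0.0286, the smallest this design allows). Among the astrocyte, oligodendrocyte and microglia lists these rose most and least (1.91 and 0.81, astrocytes 1.31). How much of each list neurons or the background hold was not tested. The difference argues against that account only under this assumption. After correction for GC content and gene length the synaptic vesicle list still had a median of -0.95, against -0.99 before, which argues against such a trend as the whole cause. Of 45 markers of other neurons, 17 fell and 1 rose (exact sign test across genes, which are not independent, p = 0.000145). Over all 19912 genes tested, 3009 fell and 2659 rose. The marker counts go against a loss confined to dopamine neurons, although dopamine neurons express some of these markers. Per library, the levels of the GABA, glutamate and serotonin, noradrenaline and acetylcholine lists gave exact permutation p of 0.4, 0.143 and 0.143. The question is therefore not settled. A smaller share of neurons together with a change in the glia, a different purity of the enriched messages, and an effect of the Ogt genotype itself may each contribute and stay open.

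The Ogt and Oga falls were set against the synaptic vesicle list, to ask whether they may be only that of neuronal messages at large. Per library, Ogt fell further than that list by a difference of -0.36 (SE 0.31, exact permutation p = 0.257), and Oga also by -0.36 (SE 0.24, exact permutation p = 0.2). The Ogt difference was -0.21 without control replicate 3 and -0.57, -0.25 and -0.17 without knockdown replicates 2, 4 and 5, and that of Oga was -0.54 and -0.19 without knockdown replicates 3 and 5. The standard errors are close in size to the differences, so whether Ogt or Oga fell further than that list cannot be told. Reads from exons of Ogt outside the floxed part would add to this uncertainty. The synaptic vesicle list differed by -1.02 in mean log2 CPM. Neuronal lists ranged from -1.154 (serotonin, noradrenaline and acetylcholine neuron markers) to -0.289 (GABA neuron markers). Ogt and Oga were not set against the other lists, so neuronal messages at large were not tested.

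Control replicate 3 stands apart from the other controls. Carry-over of whole-tissue RNA would raise astrocyte markers too, but they were lower there by a difference of -2.11 on the log2 scale (SD of the other controls 0.19). An exchange of labels with a knockdown library is argued against by the highest Ogt level of a knockdown library, 74.4 CPM, below the lowest of a control, 108.3, and a knockdown library under this label by its own 159.4 CPM. RNA of blood vessel cells in this library is a candidate source: of 40 vascular genes outside the fixed lists, 37 were highest there of all 8 libraries. Why it would hold such RNA was not tested, and a sample from outside these 8 libraries or another dissection stays open.

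Of the 35 ways to split the 8 libraries into 4 and 4, 1 gave as many changed genes as the real grouping, the real grouping itself (5668 genes); the highest of the others gave 0. The share of 1 in 35 is the smallest that this design can give. The other splits mix the groups, which puts the group difference inside each side. Chance in the grouping is therefore less likely for this count but not excluded.

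Control replicate 3 lay far from the other controls in 7 of 36 lists. Its mean log2 CPM was 6.58 for endothelial markers (others 2.27), 3.16 for pericyte and smooth muscle markers (0.33), 5.49 for astrocyte markers (7.60) and 4.71 for mitochondrially encoded messages (3.74). It was 5.06 for GABA and glycine receptors (5.69), 5.13 for clock genes (5.67) and 7.03 for splicing regulators (6.52). Among named genes it stood apart, in log2 CPM, for Cldn5 at 7.24, Rgs5 at 7.96, Rpl10a at 11.72, Gad1 at 7.96, Tph2 at 4.97, Slc6a4 at 4.07, Gjb2 at 0.14, Ccl2 at -2.43, Atp5b at 11.26 and Sqstm1 at 10.34. The same held for Nkx2-2 at 2.22, Gabrb1 at 5.51, Slc17a8 at 2.98, Rbfox3 at 6.73, Fev at 0.43, Xylt1 at 3.87, C1ql1 at 8.88, Rbm5 at 6.77, Btg2 at 5.26, Ier2 at 4.42 and Asns at 7.75.

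Among knockdown libraries, replicate 3 stood apart for glutamate receptors (5.18, others 5.74), clock genes (5.58, others 5.79), autophagy genes (6.64, others 6.77), Ccnd1 (2.63), Nmb (3.15), Prlr (0.97) and Srsf2 (6.04). Replicate 2 did so for cytosolic chaperones (6.70, others 6.96), Ddc (5.28), Mdm2 (7.05) and Rbm5 (6.20), and replicate 4 for the JAK-STAT3 list (4.97, others 5.08) and Gjb2 (4.10). Replicate 5 did so for Bcl3 (4.19) and Cdkn1a (8.10). Control replicate 6 stood apart for Cx3cr1 (-0.13) and Cep170b (10.68). All of these are log2 CPM. With 294 gene groups tested, the few genes marked in each of these libraries may be chance.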

How the results depend on the processing

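Leaving out both libraries numbered 3, the GC and length correction, and scoring the cell types under any alternative setting were not planned. The log2 fold change of Ogt kept its direction in all settings and its call in all but the non-neuronal score. Without each library in turn it was -1.61 to -1.21. The genes changed then numbered 3876 to 7198 (higher 1684 to 3723, lower 2140 to 3475), the lists 21 to 28 and the list members 317 to 520. The cell types past the adjusted permutation test numbered 0 to 7, where passing depends on how many lists reach the smallest p. The 1684 and 1736 higher genes came without control replicates 4 and 6, and 7 cell types without control replicate 3. Limma-voom called 10218 genes (5251 higher, 4967 lower; 654 members), and the edgeR fit without both libraries numbered 3 called 9565 (4805, 4760; 642); the cause was not tested. With the non-neuronal score, 0 genes (0 higher, 0 lower) and 0 members changed, 2099 genes had an unadjusted p under 0.05, and Ogt had -2.54 (adjusted p = 0.267, range over settings 9.62e-07 to 0.267); the score follows the groups. An estimated correlation left 1 list. The replicate block gave 1258 genes (480 higher and 778 lower, with 122 members) and Ogt at -1.66. Only numbers 3, 4 and 5 occur in both groups, so the other libraries add nothing to the group difference in that fit. With few degrees of freedom left, its lost calls do not tell pairing from low power. Deviations of same-numbered libraries (3, 4 and 5) correlated by 0.104, 0.099 and 0.042. Libraries numbered 3 and 4 correlated best with their own number in the other group, in both directions, and those numbered 5 did not. No label says that the numbers are pairs, so the main test used no block. Pairing is not excluded. DESeq2 left 318 adjusted p without a value.

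The score also turned the sign of the medians of oligodendrocyte markers (-0.333), neuropeptides (0.256), GABA neuron markers (0.106) and immediate early genes (0.157). It ended the list calls of oligodendrocyte markers (adjusted p = 0.102), neuropeptides (0.268), GABA (0.384), glutamate (0.136) and serotonin, noradrenaline and acetylcholine neuron markers (0.889), chaperones (0.773), glucocorticoid-responsive genes (0.185), the respiratory chain (0.335), GABA and glycine receptors (0.136) and blood (0.189). It added those of injury (0.0261), splicing (0.0335), endothelial (0.0137) and pericyte genes (0.0401). Of 143 named genes past the threshold, the block ended the calls of 70 and the score of 143.

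Reversed values, cause not tested: with the non-neuronal score, mitochondrially encoded messages -1.35, the camera direction of the pericyte list (median -2.82, negative as with no covariate), Grin2c -0.503, Bcas1 -0.092, Vcan -0.371, Cep170b -0.025 and Rpl10a 0.80; with the block, Rpl10a 0.18. Without control replicate 3, which holds the vascular signal, the endothelial list was 1.005, Cldn5 1.55, Flt1 1.30 and Rgs5 1.11 (lowest without another library: -2.474, -2.948, -3.172 and -3.218); without both numbered 3 these were 1.10, 1.51, 1.33 and 1.07; with voom the genes were 1.54, 1.26 and 0.89. The pericyte median changed sign without control replicate 3 (1.013), without both numbered 3 (1.062), with voom (0.919) and with the block (0.016). The block also ended the list calls of chaperones (adjusted p = 0.107), mitochondrially encoded messages (0.179), neuropeptides (0.12) and GABA neuron markers (0.14). With 49802305 reads or more, depth limits only genes near the floor.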

Other observations

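The comparison of the dopamine list with the synaptic vesicle list at the end of this part was chosen after the results were seen. Some receptors and channels of neurons fell. Of 38 receptors for monoamines, acetylcholine, opioids and stress peptides, 20 fell and 1, Adra2a, rose (22 and 1 adjusted over the list alone), with a camera adjusted p of 3.57e-08 and an adjusted p = 0.349 with an estimated correlation. Htr2c fell 4.21-fold, Chrnb2 3.12-fold and Oprl1, the nociceptin receptor, 2.24-fold. Of 38 channels that set firing, 18 fell and 0 rose (25 lower adjusted over the list alone), with a camera adjusted p of 7.74e-07 and an adjusted p = 0.378 with an estimated correlation. The sodium leak channel Nalcn fell 2.04-fold, Kcna2 2.09-fold and Kcnd3 2.27-fold. Of 37 glutamate receptor and scaffold genes, 13 fell and 1, Grin2c, rose (17 and 3 adjusted over the list alone), such as Grm7 (2.02-fold; 9, 8 and 9 changed without control replicate 5, control replicate 6 and knockdown replicate 2; list adjusted p = 0.00188, and adjusted p = 0.483 with an estimated correlation). Of 22 GABA and glycine receptor genes, 6 fell and 1, Gabrb1, rose (7 and 1 adjusted over the list alone), such as Gabra3 (2.06-fold; in mean log2 CPM control replicate 3, at 5.058, lay below 3 of the 4 knockdown libraries, exact permutation p = 0.114; list adjusted p = 0.0205, and adjusted p = 0.483 with an estimated correlation). Of 36 neuropeptide precursor and processing genes, 11 fell and 3 rose (11 and 3 adjusted over the list alone), with Vgf down 2.83-fold and the processing enzyme gene Cpe up 3.02-fold, with Pomc and Nmb also up. That list had a camera adjusted p of 0.0228 and an adjusted p = 0.483 with an estimated correlation; without knockdown replicate 2 the adjusted p was 0.0897. The call of Adra2a was lost without knockdown replicate 4 (adjusted p = 0.0509). Pomc and Nmb were chosen after their values were seen. The calls of Grin2c, Gabrb1 and Nmb were each lost without any of at least 5 single libraries, with adjusted p of up to 0.105 (without knockdown replicate 2), 0.119 (knockdown replicate 2) and 0.103 (control replicate 6). Microglia, astrocyte and oligodendrocyte markers were higher in the same libraries, with median log2 fold changes of 2.27, 1.02 and 0.84.

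Some members of stress and activity lists changed, in both directions. Of the lists given here, only the cytosolic chaperones passed camera with all libraries. Of 22 cytosolic chaperones, 6 fell and 2 rose (6 and 2 adjusted over the list alone), with Hspa8 down 2.46-fold and Cryab, also an oligodendrocyte marker, up 4.33-fold, with Hspb8 also up. That list had a camera adjusted p of 0.0228 and an adjusted p = 0.483 with an estimated correlation; without knockdown replicate 2 the adjusted p was 0.0606, and with the strict filter 0.064 and with the non-neuronal score 0.773. The mean log2 CPM of astrocyte, oligodendrocyte and microglia markers was higher in the knockdown libraries, by 1.31, 0.81 and 1.91 (astrocytes 0.78 without control replicate 3). Of 25 immediate early genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.569), with Egr1 (2.44-fold), Nptx2 and Ier2 down and Jun (1.77-fold), Ier5, Gadd45b and Btg2 up. Of 24 neuronal injury genes 10 rose and 4 fell (10 and 4 adjusted over the list alone; adjusted p = 0.0893, 0.0362 with the strict filter, and 0.0329 without control replicate 3, where it was 0.465 with an estimated correlation). The 4 that fell were Vgf, Ecel1, Sprr1a and Gap43. Of 29 unfolded protein response genes 6 rose and 3 fell (6 and 3 adjusted over the list alone; adjusted p = 0.435), with Slc7a11 up 2.76-fold and Xbp1 (1.73-fold), Asns and Sel1l down. Of 29 autophagy and lysosome genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.358). The lysosomal genes Lamp1 and Ctsd rose 1.83-fold and 2.02-fold, with Ctsl and Lamp2 also up, and Sqstm1 (1.90-fold) and Gabarapl1 fell. Of 34 splicing regulators 0 rose and 5 fell (0 and 2 adjusted over the list alone; adjusted p = 0.0874, and 0.662 with an estimated correlation), namely Tra2b, Ddx5, Rbm39, Srsf2 and Rbm5. This list passed without control replicate 4 (adjusted p = 0.034), 5 (0.0286) or 6 (0.0465) or knockdown replicate 3 (0.0301), with no filter on low counts (0.0155) and with the replicate block (0.0414). Without control replicate 3, which stood apart for this list, the adjusted p was 0.433 and the median log2 fold change 0.035, against -0.216 with it. The 5 became 2 or 3 without control replicate 4 (2), 5 (3) or 6 (2) or knockdown replicate 4 or 5 (2 each). Of 19 circadian clock genes 1 rose, Npas2 (1.95-fold), and 0 fell (1 adjusted over the list alone; adjusted p = 0.435), and 2 changed without control replicate 3 or knockdown replicate 3. The 9 unfolded protein response genes became 4 without control replicate 4 and 5 without knockdown replicate 4 or 5. The 14 injury genes became 9 without control replicate 4 or knockdown replicate 4. Gadd45b, Btg2, Ier2, Ctsl, Lamp2, Gabarapl1, Ecel1, Gap43, Sel1l, Hspb8 and Rbm5 were chosen after their values were seen. Several of these gene calls were lost without any of at least 4 single libraries. Their highest adjusted p came without control replicate 4 for Btg2 (0.119), without control replicate 6 for Sel1l (0.0937) and Srsf2 (0.135), without knockdown replicate 2 for Ier2 (0.0911), without knockdown replicate 3 for Lamp2 (0.0751) and without knockdown replicate 4 for Rbm39 (0.0615) and Rbm5 (0.0949). The Hspb8 call was lost without control replicate 6 (0.0536) or knockdown replicate 5 (0.0692).

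Cep170b and Rpl10a were chosen after their values were seen. Cep170b rose from 2000 ± 240 to 5004 ± 2151 CPM (SD, n = 4, edgeR adjusted p = 0.00566). Whether transcripts of the viruses were counted at these 2 genes was not tested, which would need the reads. Rpl10a had 0.328% of the reads of control replicate 3, 1.27% to 1.29% of those of the other controls and 0.793% to 1.24% of those of the knockdown libraries. An unnamed gene (ENSMUSG00000119584), also chosen afterwards, held 1.61% of the reads of control replicate 3 and 1.09% of those of knockdown replicate 3, against 0.183% to 0.531% in the other libraries. Per library, the dopamine list differed from the synaptic vesicle list between groups by -0.09 on the log2 scale (SE 0.17, exact two-sided permutation p = 0.743). Without control replicate 3 the difference was 0.05, of the other sign, without control replicate 4, control replicate 6 or knockdown replicate 4 it was -0.18, -0.14 and -0.14, and without knockdown replicate 2 it was -0.03.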
